A study of Mus musculus with 2 samples.

How the data were processed

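RNA from dissected ureters of mouse embryos at E14.5 (embryonic stage in days) was measured on 2 two-colour Agilent arrays. Per the labels, 1 channel of each array held RNA of Smad4cKO embryos (Tbx18(cre/+);Smad4(fl/fl), NMRI strain) and the other channel RNA of control embryos (Tbx18(+/+);Smad4(fl/+)). In this design Cre recombinase made from the Tbx18 locus removes Smad4, the shared partner of BMP and TGFB signalling SMADs, from the ureteric mesenchyme. The 200 ng of total RNA per channel was amplified and labelled with AlexaFluor555 (read as green) or AlexaFluor647 (read as red), per the labels' protocols. Array 1 paired female embryos, with the labelled control in red. Array 2 paired male embryos, with the labelled Smad4cKO in red. Dye orientation and sex therefore changed together, and 2 arrays limit the precision of each value. The labels do not say how many embryos entered each RNA or whether the pairs came from separate litters, so errors say nothing of the spread between litters.

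The deposited scanner files were made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Per the file headers, they hold an intensity for each spot and channel (mean signal, background median and processed signal). The deposited log10 ratio of red over green and the p-value of that ratio come from the same software, per the file headers. Its processed signals were background-subtracted and dye-normalized with LOWESS. Flags mark outlier spots, saturation and spots well above background. Both arrays lay on 1 slide and share 1 scan, so no batch by slide or scan exists. The authors' deposited value table holds a signed fold between the channels: a ratio of at least 1, or minus the inverse of a ratio under 1. Its scale and direction were found by setting each column against the processed signals. Its log2 values differed from theirs by a constant of -0.00314 on array 1 and 0.0111 on array 2. The largest departure from that constant was 7.25e-10 over 22004 probes on array 1 and 7.17e-10 over 22529 probes on array 2. The median of each column was 1. It is red over green on array 1 and green over red on array 2, which by the dye labels is control over Smad4cKO on both arrays, while the titles name Smad4cKO first. The software that made it is not given in the sources used here.

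The mean signals were background-corrected with normexp (offset 50) and normalized within each array by loess, with control spots at weight 0 (limma 3.58.1 with statmod 1.5.0, R 4.3.3, files read with the R package data.table, version 1.17.8). Ratios were turned to labelled Smad4cKO over labelled control on both arrays. The 1377 control spots among 44397 spots were left out, as were spots marked as outliers (237 on array 1 and 221 on array 2, of 43020). Spots of a probe were averaged. A probe was tested where the same labelled group was well above background on both arrays, which held for 26670 of 39429 probes. The brightest tested probe stood for a gene, giving 21238 genes, 15086 of them with a gene name. Accessions of 26412 probes were matched, without versions, to symbols of a RefSeq gene table (assembly GRCm38.p6). Other probes kept the name in the file, and 12933 had no gene name. Coordinates are those of the scanner files (build mm9).

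Each gene's log2 ratios were tested against 0 with limma (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05), which had 1 residual degree of freedom and 4.89 prior degrees of freedom. The SE is limma's moderated standard error, which rests mostly on the spread pooled over all genes and not on the gene's own 2 values. A second, untested rule asked for at least 1.5-fold in the same direction on both arrays. Its background is the number of genes at 1.5-fold in opposite directions, which holds dye bias, any difference between the sexes and noise. A bias fixed to a dye gives opposite signs in this design, so it can raise this background without adding genes in the same direction. No p-value is given for it, since turning the signs of 2 arrays allows none below 0.5. A total of 28 gene lists was fixed before the data were examined, and the 27 with at least 5 tested members were tested with camera (two-sided, preset inter-gene correlation 0.01). Where 1 labelled group was not well above background on either array, a fold was taken from channel values after loess and Aquantile. The dim channel was raised only to the lowest level of any probe well above background. For Sult1e1 this left the fold as it was, so the fold is an estimate and not a lower bound. It is also open to dye bias.

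Named genes follow a rule fixed at the same time as the lists. Smad4 and Tbx18 are named in any case. Then up to 12 genes per direction are named: those past limma, and after them those past the 1.5-fold rule, ordered by the smaller of the absolute log2 ratios of the arrays. Up to 4 members per list with the same sign on both arrays are added in that order. Genes without a symbol are counted and not named. A few other genes are named, and are said to have been chosen after their values were seen.

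Alternatives covered the background correction, within-array normalization, processed signals, the authors' value table, the filter on dim probes, the rule for probes of a gene, outlier spots, each array alone, the limma settings, a separate-channel fit, the fold threshold and the list test. Removal of a smooth trend on the GC and T shares of the probe on each array, with the GC trend free to vary with brightness, was chosen after seeing the data. The functions were tested on simulated data with the comparison's own design and 21238 genes. The changed genes were brighter than the median gene, noise was independent between probes, and the dye effect was smooth in brightness. Of 50 changed genes per size, limma called 2 at 1.5-fold, 24 at 2-fold, 49 at 4-fold and 50 at 8-fold. The 1.5-fold rule found 11, 42, 50 and 50 of them. Among 21020 unchanged genes, limma called 6, the rule 59, and 46 passed it in opposite directions. The real arrays had 266 genes in opposite directions, so the simulated rates may not carry over to them or to dim genes. A simulated list shifted by 0.5 on the log2 scale was called by camera with the preset correlation, and 0 of the other lists were. The estimated correlation and fry called 0 lists there, so both missed the shifted list. The simulated genes varied independently, so the 0 other lists called do not cover lists whose genes vary together.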

Results

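Gene expression was compared between ureters of Smad4cKO and control mouse embryos at E14.5 on 2 two-colour arrays, a female pair on array 1 and a male pair on array 2, with the dyes exchanged between them. The comparison asks which transcripts differ when Smad4 is deleted in the Tbx18-expressing mesenchyme of the ureter, the tissue that forms its smooth muscle coat and fibrous layers. The mutants also carry 1 Tbx18 allele with Cre, which the controls lack. Effects of that allele cannot be told apart from those of Smad4 loss. In the channel labelled Smad4cKO, 70.3% of spots on array 1 and 69.0% on array 2 were well above background. In the channel labelled control these shares were 68.3% and 70.1%. Median signal over background lay between 8.76 and 10.8 across the 4 channels, and 0 spots were saturated. The Y-linked genes Ddx3y and Eif2s3y gave processed signals of 3512 and 6118 in the labelled Smad4cKO channel of the male pair, and were not well above background in the female pair.

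The loci at which the genotypes differ did not settle the direction of the ratios. All ratios are given as labelled Smad4cKO over labelled control, by the dye labels. Smad4 gave a log2 ratio of -0.69 on array 1 and -0.14 on array 2 (mean -0.42, SE 0.17, n = 2, limma adjusted p = 1). Its probe lies at chromosome 18, 73798670 to 73798729 (mm9), and a second Smad4 probe gave -0.31 and -0.49. Which part of Smad4 the deletion removes is not stated in the labels, so these probes may lie outside it and then check nothing. Tbx18, of which the mutants carry 1 allele with Cre, gave 0.07 and 0.81 (mean 0.44, SE 0.20, n = 2, limma adjusted p = 1) at chromosome 9, 87599514 to 87599573. The authors' deposited table holds the inverse ratio under titles that name Smad4cKO first. Read as titled, it has the opposite direction: Myh11 has a signed fold of -4.66 and -7.30 there, and Smad4 1.69 and 1.07. The dye labels are followed throughout, and "the channel labelled" is kept for each direction. If the dye labels were exchanged on both arrays, every brighter below becomes dimmer and the reverse, and sizes and tests stay as they are.

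By the dye labels, the genes brighter in the channel labelled Smad4cKO included contractile genes of smooth muscle and BMP response genes. Myh11, the smooth muscle myosin heavy chain, gave 2.37 ± 0.18 (log2, SE, n = 2), or 5.15-fold. Cnn1, which encodes the actin-binding protein calponin, gave 1.91 ± 0.17, and Actg2, the enteric smooth muscle actin, gave 1.75 ± 0.19. Smad9, a receptor-regulated SMAD of the BMP pathway, gave 1.53 ± 0.13. Id1, a BMP-induced inhibitor of helix-loop-helix transcription factors, gave 1.17 ± 0.13. The hormone gene Sct gave 1.94 ± 0.19, and Hpgd, whose product degrades prostaglandins, gave 1.57 ± 0.13. The potassium channel gene Kcnk3 (1.59 ± 0.14), the carbonic anhydrase gene Car3 (1.60 ± 0.15), Elmod1 (1.53 ± 0.14) and the transcription factor gene Irf5 (1.34 ± 0.13) completed the group with Fbxl22 (1.83 ± 0.23). A second tested probe of Fbxl22 gave 0.04, so its probes disagree, and with the mean of its probes the log2 ratio of Fbxl22 was 0.94.

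In the other direction, Fndc1, a gene for a protein with fibronectin type III domains, was the only gene past limma's threshold. It gave -2.35 ± 0.13 (log2, SE, n = 2, limma adjusted p = 0.0484) at chromosome 17, 7931560 to 7931619, with -2.38 on array 1 and -2.32 on array 2. The call on the log2 ratio of Fndc1 was lost without background subtraction (limma adjusted p = 0.188), with median centring (1), with the mean of a gene's probes (0.0747) and with outlier spots kept (0.0564). Gdnf, the ligand of the Ret receptor in ureteric bud outgrowth, gave -1.95 ± 0.15, and the prokineticin receptor gene Prokr2 gave -1.90 ± 0.14. The homeobox gene Evx1 (-1.37 ± 0.14), the metalloprotease gene Adamts18 (-1.33 ± 0.13) and the proteoglycan gene Kera (-1.29 ± 0.15) were also dimmer in the channel labelled Smad4cKO. So were the potassium channel gene Kcnd3 (-1.34 ± 0.16), Efcab3 (-1.37 ± 0.15), Unc13c (-1.30 ± 0.14) and the helix-loop-helix gene Msc (-1.15 ± 0.13). Efcab3 and Msc were well above background in the channel labelled Smad4cKO on 1 array only, and from processed signals the log2 ratio of Efcab3 was -2.48 and the log2 ratio of Msc -2.15. Sult1e1, an oestrogen sulfotransferase gene, was not well above background in the channel labelled Smad4cKO on either array. It gave -1.45 ± 0.15, or 2.74-fold brighter in the labelled control, an estimate that rests on a channel near background. Ramp1, part of the calcitonin gene-related peptide receptor, gave -1.16 ± 0.13, but another tested probe gave 0.01, and with the mean of its probes the log2 ratio of Ramp1 was -0.57. Among the 24 genes named in both directions, those other than Fndc1 had limma adjusted p between 0.0656 and 0.118.

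**Figure D1:**
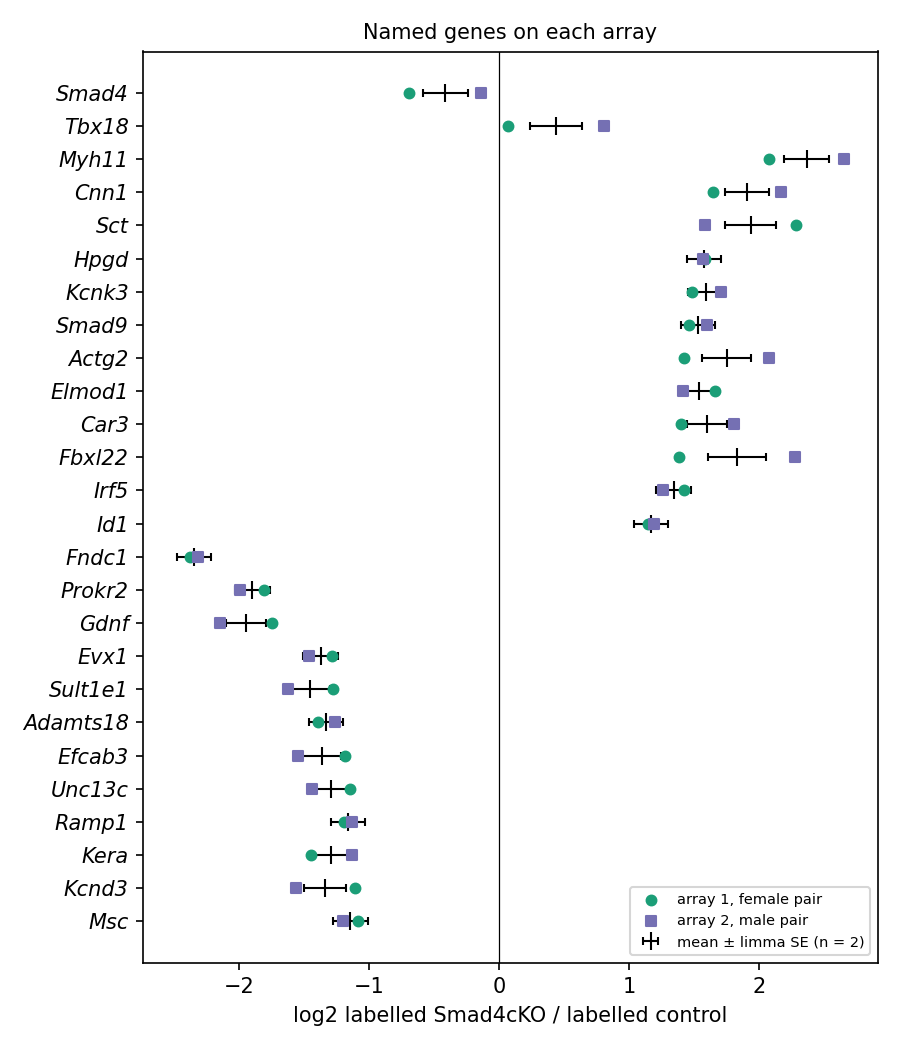
Log2 ratio of labelled Smad4cKO over labelled control for Smad4, Tbx18 and the 24 genes named by the rule, with circles for array 1 (female pair), squares for array 2 (male pair), and a bar for the mean ± limma SE (n = 2). The ratios of Myh11 are 2.08 and 2.65, those of Fndc1 -2.38 and -2.32.

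Across all 21238 genes, limma called 0 genes brighter and 1 gene dimmer in the channel labelled Smad4cKO. At an unadjusted p under 0.05 the numbers were 455 and 630, against 1062 expected by chance in all. The 1.5-fold rule found 104 genes brighter and 111 dimmer on both arrays, 12 and 18 of them without a gene name. A further 266 genes passed 1.5-fold in opposite directions on the arrays, more than in the same direction, and this order depended on the processing. Of the 266, 261 were brighter in red on both arrays and 5 in green. A bias fixed to a dye gives opposite signs here, so the 266 may overstate how many same-direction genes noise gives. From processed signals 180 genes were opposite against 184 brighter and 199 dimmer, 186 against 177 and 184 from the authors' values, 230 against 130 and 151 with normexp offset 10, and 1440 against 91 and 99 with median centring. At 2-fold, 21 genes were brighter and 25 dimmer, against 28 in opposite directions, and at 3-fold 2 and 4 against 0. The arrays' ratios correlated across genes at -0.07 (Pearson) and -0.20 (Spearman), where genes are not independent replicates. Pearson's r was -0.42 among genes at or above the median brightness and 0.33 below it. Limma's counts depended on the processing, from 0 brighter and 0 dimmer genes with median centring to 143 and 160 from Feature Extraction's processed signals and 298 and 407 with an intensity trend and robust empirical Bayes.

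**Figure D2:**
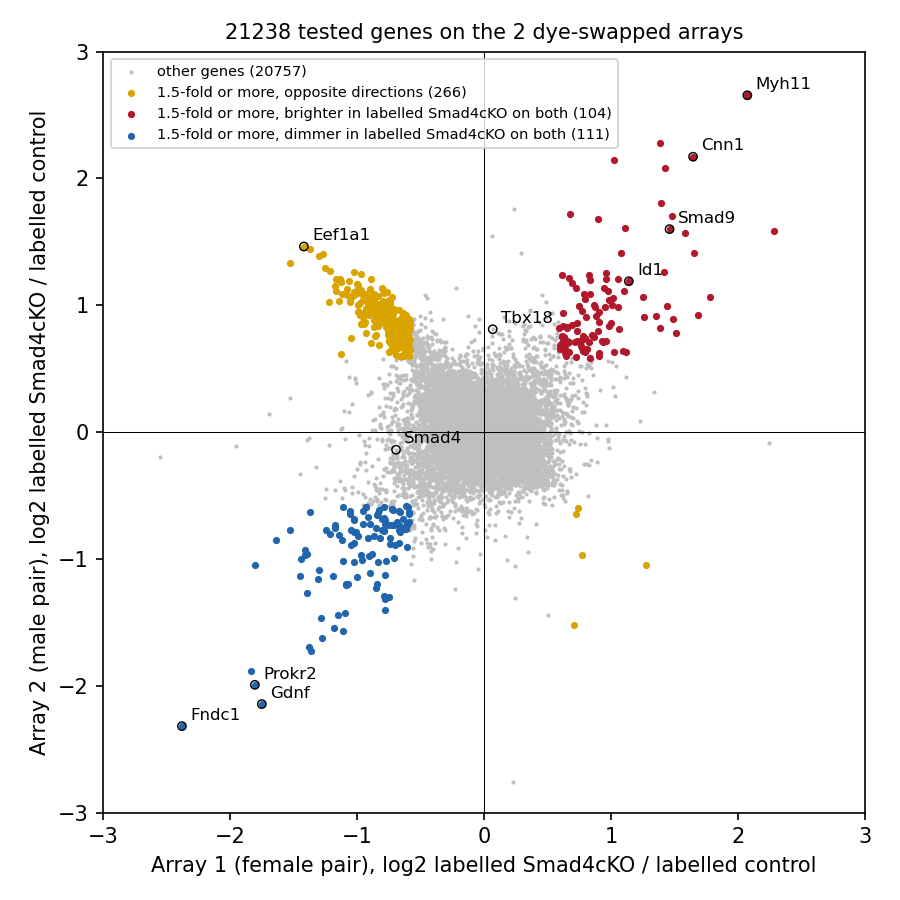
Log2 ratio of labelled Smad4cKO over labelled control of each of the 21238 tested genes on array 1 (horizontal) and array 2 (vertical), 1 point per gene. Genes at or beyond 1.5-fold are coloured: 104 brighter on both arrays, 111 dimmer on both and 266 in opposite directions, most of these at the upper left.

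Among 19 tested BMP-SMAD target genes, 5 were brighter in the channel labelled Smad4cKO by the 1.5-fold rule. These were Smad9, Id1, Id2 (1.20 ± 0.25, with 0.68 on array 1 and 1.72 on array 2), Id3 (1.02 ± 0.13) and Smad6 (0.78 ± 0.15), and 1, Zcchc12 (-0.66 ± 0.13), was dimmer; Smad6 and Zcchc12 were chosen after their values were seen. The same numbers, 5 and 1, passed limma adjusted over the list alone, and 0 passed over all genes tested. The list's median was 0.04, near 0, with -0.0026 on array 1 and 0.10 on array 2, and camera called it in favour of the channel labelled Smad4cKO (adjusted p = 0.0185, and adjusted p = 0.796 with an estimated correlation). With median centring that call was lost (adjusted p = 0.148). Among 39 smooth muscle contractile and cytoskeletal genes, 20 were brighter on both arrays and 8 dimmer. The other 11 changed sign between arrays 1 and 2, among them Myl9 (0.28 and -0.26), Tpm1 (-0.17 and 0.20) and Cald1 (-0.50 and 0.27). The 8 brighter by the 1.5-fold rule included Myh11, Cnn1, Actg2 and the muscarinic receptor gene Chrm3 (1.24 ± 0.15). They also included Acta2 (1.59 ± 0.26, with 1.03 on array 1 and 2.14 on array 2), Mylk (0.94 ± 0.13) and Des (0.71 ± 0.13). Pcp4 (-0.79 ± 0.15) was dimmer by the rule, and Pdlim3 (-0.68 ± 0.15) was dimmer without passing it. Of these, Myl9, Tpm1, Cald1, Acta2, Mylk, Des, Pcp4 and Pdlim3 were chosen after their values were seen. Adjusted over the list alone, limma called 10 brighter and 2 dimmer, and camera called the list (median 0.16, with 0.03 on array 1 and 0.27 on array 2, adjusted p = 1.96e-07, and adjusted p = 0.796 with an estimated correlation). Of the 27 lists, camera called 9 at the preset correlation and 0 with an estimated correlation, and fry called 0. The estimated correlation and fry have little power at 1 residual degree of freedom, and both missed the simulated list shifted by 0.5. Their 0 calls therefore do not count against a list. The preset 0.01 lies below the correlations estimated for BMP targets (0.30) and smooth muscle genes (0.33), so its calls may be too many. Those estimates rest on the same 1 degree of freedom.

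Several lists of markers of other cell types were also called by camera at the preset correlation, each with adjusted p = 0.796 with an estimated correlation. Among 22 neuronal, glial and neural crest markers, 18 were dimmer in the channel labelled Smad4cKO on both arrays (median -0.51, with -0.80 on array 1 and -0.27 on array 2, adjusted p = 1.51e-14, and adjusted p = 0.796 with an estimated correlation). Adjusted over the list alone, limma called 12 dimmer and 1 brighter. The neuronal intermediate filament genes Prph (-0.86 ± 0.15), Nefm (-0.85 ± 0.15) and Nefl (-0.85 ± 0.16) and the transcription factor gene Hand2 (-0.74 ± 0.14) passed the 1.5-fold rule. The glial gene Sox10, chosen after its value was seen, gave -0.25 ± 0.13. Among 21 kidney and nephric markers the median was -0.08 (adjusted p = 0.0163, and adjusted p = 0.796 with an estimated correlation), with Gdnf and Wt1 (-0.98 ± 0.15) past the 1.5-fold rule and Ret at -1.45 on array 1 and -0.33 on array 2. Skeletal muscle, fat, liver and mesothelial markers had a median of -0.08 over 16 genes, with -0.16 on array 1 and -0.11 on array 2 (adjusted p = 0.00782, and adjusted p = 0.796 with an estimated correlation), with the embryonic myosin gene Myh3 (-0.72 ± 0.13) and Myog (-0.63 ± 0.15). Erythroid markers had a median of -0.06 over 14 genes, with -0.19 on array 1 and -0.13 on array 2 (adjusted p = 0.0467, and adjusted p = 0.796 with an estimated correlation), with Gata1 at -0.52 ± 0.13. That call was lost with probes above background in both channels (adjusted p = 0.0817). The globin genes Hba-a1 (-0.86 and 0.94) and Hbb-bt (-0.98 and 0.95), chosen after their values were seen, had opposite signs on the arrays, and with processed signals the log2 ratio of Gata1 was -0.83. In the other direction, 17 macrophage and leukocyte markers had a median of 0.18 (adjusted p = 6.05e-05, and adjusted p = 0.796 with an estimated correlation), with Mrc1 at 0.42 ± 0.13. Their median was 0.32 on array 1 and 0.02 on array 2. The 37 urothelium genes had a median of 0.13, with 0.12 on array 1 and 0.06 on array 2 (adjusted p = 0.0163, and adjusted p = 0.796 with an estimated correlation), with Cldn3 at 0.34 ± 0.13 and Krt20 at -0.46 ± 0.14. That call was lost with processed signals (adjusted p = 0.0601). The 20 endothelial markers had a median of 0.11 (adjusted p = 0.0163, and adjusted p = 0.796 with an estimated correlation), with Ramp2 at 0.55 ± 0.13. In the macrophage, urothelium, endothelial and erythroid lists 0 genes passed the 1.5-fold rule or limma adjusted over the list alone. In the kidney list and in the skeletal muscle, fat, liver and mesothelial list, 0 brighter and 2 dimmer genes passed limma adjusted over the list alone.

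**Figure D3:**
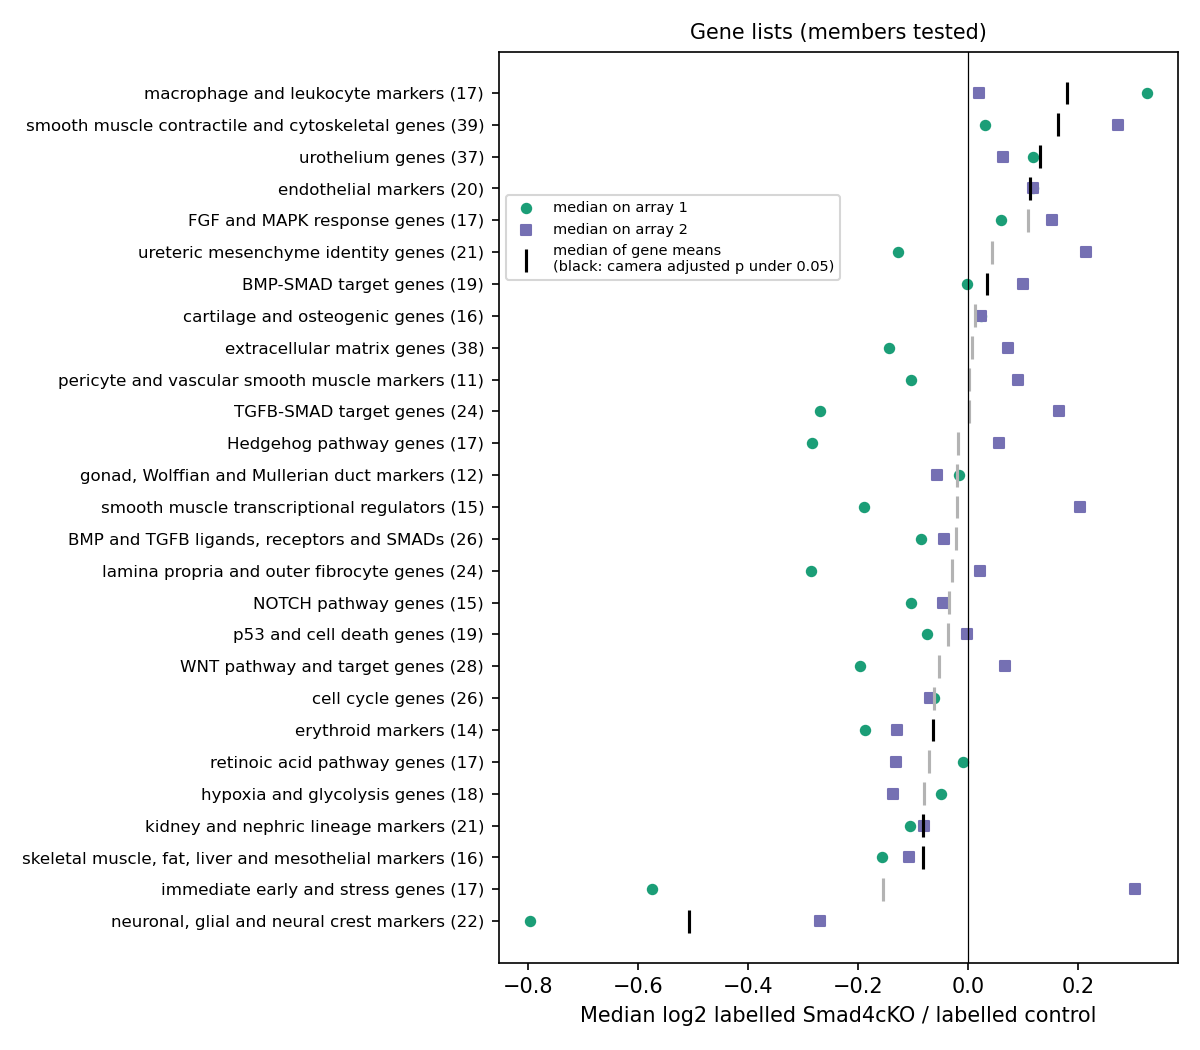
Median log2 ratio of labelled Smad4cKO over labelled control for each of the 27 tested gene lists (members tested in brackets) on array 1 (circles), on array 2 (squares) and of the mean over the arrays (bars, black where camera's adjusted p was under 0.05 at the preset correlation). Neuronal, glial and neural crest markers sit at -0.80 and -0.27, immediate early and stress genes at -0.57 and 0.30.

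The other lists were not called by camera, though single members had large ratios. Among regulators of smooth muscle (adjusted p = 0.61), Myocd, the coactivator that drives contractile genes, gave 1.29 ± 0.21, and Hand2 was dimmer. Their median (-0.02) and mean (0.06) differ in sign. Among BMP and TGFB ligands, receptors and SMADs (adjusted p = 0.647), Bmp5 gave 1.13 ± 0.13, and Inhba (-0.79 ± 0.13) was dimmer by the 1.5-fold rule. Bmp4 (-1.04 on array 1 and -0.43 on array 2) and Bmp2 (-0.48 ± 0.13) passed neither that rule nor limma. The TGFB-SMAD target genes (adjusted p = 0.61) had 0 of 24 members past the 1.5-fold rule, with Snai2 at 0.51 ± 0.15. Snai1 gave 0.34 on array 1 and 0.82 on array 2, and Lox gave -0.67 and -0.31. Among lamina propria and outer fibrocyte genes (adjusted p = 0.259), Dpt (-1.25 ± 0.21), the retinoic acid-synthesising Aldh1a2 (-1.02 ± 0.17) and Gdf10 (-0.73 ± 0.13) were dimmer and passed the rule. Of the retinoic acid pathway genes (adjusted p = 0.0997), 2 were brighter and 2 dimmer by the rule, with Cyp26a1, which degrades retinoic acid, at -0.93 ± 0.14 and Rbp4 at 0.81 ± 0.13. Extracellular matrix genes (adjusted p = 0.235) had 3 members dimmer by the rule: Col8a1 (-1.17 ± 0.16), Tnc (-1.37 and -0.63 on arrays 1 and 2) and Mfap4 (-0.81 ± 0.13). From processed signals the log2 ratio of Col8a1 was -1.76. WNT pathway and target genes (adjusted p = 0.118) held Rspo1 at -1.22 ± 0.16, Wnt5a at -0.60 ± 0.13 and Sfrp2 at 0.61 on array 1 and 1.23 on array 2. Among FGF and MAPK response genes (adjusted p = 0.118), Fgf18 gave -1.01 ± 0.14 and Fgf10 0.48 ± 0.13. Ureteric mesenchyme identity genes (adjusted p = 0.787) held Hoxd12 (-0.79 ± 0.13) and Hoxd11 (-0.67 ± 0.13), with Tcf21 at 0.92 on array 1 and 0.33 on array 2. Their median (0.04) and mean (-0.03) differ in sign. A second tested probe of Hoxd11 gave smaller ratios, -0.22 on array 1 and -0.47 on array 2. Cartilage and osteogenic genes (adjusted p = 0.235) held Hapln1 (0.81 ± 0.13) and Alpl (0.94 ± 0.16). Adjusted over the list alone, limma called 2 brighter and 5 dimmer retinoic acid genes, 3 and 2 cartilage genes, 2 and 1 smooth muscle regulators, 1 and 2 WNT genes, 1 and 1 FGF genes, and 1 and 1 BMP and TGFB ligands. It called 0 brighter and 3 dimmer genes in both the lamina propria and the extracellular matrix list, and 0 and 2 among ureteric mesenchyme genes. The extracellular matrix list had a median of 0.0070 and a mean of -0.08.

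The Hedgehog, NOTCH, cell cycle, hypoxia and glycolysis lists each had a camera adjusted p of 0.151 and 0 members past the 1.5-fold rule. In the Hedgehog list Sfrp1 gave -0.59 ± 0.15 and in the NOTCH list Jag1 gave -0.57 on array 1 and -0.24 on array 2. The median of the 26 cell cycle genes was -0.06. P53 and cell death genes (adjusted p = 0.644), with Cdkn1a at -0.38 ± 0.13, pericyte and vascular smooth muscle markers (adjusted p = 0.61), with Kcnj8 at -0.55 ± 0.13, Rgs5 at -0.55 ± 0.14 and Angpt1 at 0.51 ± 0.13, and gonad and duct markers (adjusted p = 0.235), with Inhba past the 1.5-fold rule, were not called. Adjusted over the list alone, limma called Angpt1 brighter and Kcnj8 and Rgs5 dimmer among the pericyte markers (adjusted p = 0.0298 for each), and Inhba dimmer among the gonad and duct markers (adjusted p = 0.0117). The TGFB-SMAD targets had a median of 0.0012 and a mean of -0.03, and the pericyte markers a median of 0.0016 and a mean of -0.04. Immediate early and stress genes (adjusted p = 0.118) differed between the arrays, with a median of -0.57 on array 1 and 0.30 on array 2. Of its 17 members, 14 changed sign between the arrays. Both medians lie on the side brighter in red, as do 261 of the 266 genes in opposite directions. Dye and sex cannot be told apart for this list.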

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

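The test of probe base composition was written down before its result was seen; all the other tests in this part were chosen after the results they bear on had been seen. Genes named only in this part were chosen after their values were seen.

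By the 1.5-fold rule, 5 of 19 BMP targets (list median 0.04) and 8 of 39 smooth muscle genes were brighter in the channel labelled Smad4cKO and 1 of each list was dimmer, although SMAD4 is known to carry BMP signals; camera calls both lists at the preset correlation, with adjusted p = 0.796 with an estimated correlation, and the BMP call is also lost with median centring (adjusted p = 0.148). An exchange of the dye labels on both arrays is a candidate explanation: Tbx18, intact on 1 allele in the mutants, gave a mean of 0.44 (0.07 on array 1 and 0.81 on array 2). Against it, Smad4 gave a mean of -0.42 (-0.69 and -0.14) and both of its probes were dimmer in the channel labelled Smad4cKO on both arrays, which goes with dye labels that are right. The Smad4 and Tbx18 ratios have limma adjusted p of 1, and which exons the probes and the deletion cover is not known here. The authors' deposited table is control over Smad4cKO by the dye labels on both arrays. Read as titled, it goes with an exchange: Id1 has signed folds of -2.10 and -2.42 there, and Smad4 1.69 and 1.07. That the titles give the order of the ratio is assumed in this reading. The exchange and the labelled direction cannot be told apart from these values, and a biological reversal stays open as untested.

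The 266 genes at or beyond 1.5-fold in opposite directions in the female and the male pair stood out because the 1 array of each sex moved the other way; that difference was not tested. They include Eef1a1 (-1.42 and 1.46 on arrays 1 and 2), Col1a1 (-1.37 and 1.44) and Junb (-0.74 and 0.64), and 261 of them were brighter in red on both arrays, with 97.4% brighter than the median gene, which argues against noise near background. A dye bias that follows probe composition is consistent with the red over green component, which correlated with the GC share of the probe at -0.34 across 21238 genes (Spearman), against 0.13 for the genotype component. A red bias of the brightest spots left after loess also has its values, as 77.8% of the 266 were brighter in red and among the brightest 5% of genes. With the composition trend removed, 144 genes were opposite, 135 of them among the 266, so that trend does not account for all of them. That fit let brightness act only through the GC trend, so it may have taken out part of a brightness bias. The 144 genes therefore cannot tell a red bias of the brightest spots from a difference between the sexes. With processed signals, 127 of the 266 genes stayed opposite. A difference between the sexes gives no reason for 77.8% of the 266 to lie on the red side and among the brightest 5%. Those values argue against it as the source of most of the 266. For single genes such a difference, which changed together with the dyes, stays open.

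Neuronal markers were dimmer in the channel labelled Smad4cKO, a direction that turns if the dye labels were exchanged. Less nerve or ganglion tissue in that dissected material could lower neuronal and glial transcripts together. The 13 neuronal markers had a mean of -0.61 (SD 0.27 over genes), with -0.85 on array 1 and -0.38 on array 2, and among them Stmn3 gave -0.85 and Th -0.09. The 6 glial markers, with Sox10 at -0.25, had a mean of -0.10 (SD 0.19 over genes), a difference of 0.51 that was 0.71 on array 1 and 0.31 on array 2 (exact permutation test over genes, two-sided, p = 0.000995, for the mean of the arrays, where genes of 1 tissue are not independent). Equal loss of both is argued against, but glial cells elsewhere in the ureter could hide a small loss, and the bound of this test was rewritten after a first version, which came out against the explanation, had wrongly compared levels of different probes; uneven dissection and a difference between the labelled genotypes cannot be told apart.

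Among the processed signals, which the main test does not use, Xist gave 182.9 in the channel labelled Smad4cKO of the male pair, against 9.43 in its labelled control, where it was not well above background. A second Xist probe gave 44.6 against 7.25 there, and in the female pair the first probe gave 3344 and 3366. In the male pair the Y-linked Ddx3y gave 3512 in the channel labelled Smad4cKO against 3687 in the labelled control, and Eif2s3y 6118 against 5804. The sex of array 2 is taken from the labels, and whether its channel labelled Smad4cKO also held female material was not tested.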

How the results depend on the processing

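Removal of the probe composition trend was chosen after seeing the data, and directions are by the dye labels in every setting. Limma's 0 brighter and 1 dimmer genes became 35 and 31 with normexp offset 10, 143 and 160 with Feature Extraction processed signals, 72 and 77 with the authors' value table, 298 and 407 with an intensity trend and robust empirical Bayes, 9 and 9 at adjusted p 0.10, and 1 and 3 with probes above background in both channels. With the probe composition trend removed they were 5 and 3. The dimmer count was 0 without background subtraction, with median centring, with the mean of a gene's probes and with outlier spots kept, where Fndc1 no longer passed. A separate-channel fit with a dye term and no replicate block called 0 and 0, with 1952 genes at an unadjusted p under 0.05; the same fit with the array correlation was planned and could not be fitted, since that correlation went to 1. Limma and camera have no test without a replicate. The 104 brighter and 111 dimmer genes of the 1.5-fold rule were 184 and 199 with processed signals, 177 and 184 with the authors' value table, 21 and 25 at 2-fold, 234 and 310 at 1.3-fold, and 162 and 185 where the scanner's error model gave p under 0.01 on both arrays. Leaving out 1 array gave 256 to 635 brighter and 242 to 684 dimmer genes, since the rule then asks less; 635 and 242 were without array 1 and 256 and 684 without array 2. Of the 9 lists camera called, 0 passed with an estimated correlation and 0 with fry. The medians of 15 lists lay outside the central range of random lists, some of them lists that camera did not call, such as cell cycle genes. The median of the BMP-SMAD targets lay inside that range, at percentile 86.46, and those of the other lists camera called lay outside it. With an estimated correlation 0 lists had even an unadjusted camera p under 0.05, so that setting could hardly call any list at 1 residual degree of freedom. At the preset correlation, the call was lost for BMP-SMAD targets with median centring (adjusted p = 0.148), for urothelium genes with processed signals (0.0601) and for erythroid markers with probes above background in both channels (0.0817). The Pearson correlation of the arrays, -0.07, was -0.119 without background subtraction, -0.0126 with offset 10, -0.529 with median centring, 0.115 with processed signals, 0.0921 with the authors' value table, -0.0941 with probes above background in both channels, -0.0446 with the mean of a gene's probes and 0.0191 with the composition trend removed. The threshold and single-array settings change the counts by their own construction; for the others the cause was not tested. Most named genes were chosen for the same sign on both arrays, so leaving out an array cannot reverse them. Eef1a1, Col1a1, Junb, Myl9, Tpm1, Cald1, Hba-a1 and Hbb-bt, which differ in sign, are not counted. Over 143 named genes and 1568 alternatives that use both arrays, 0 directions reversed, 251 gave a gene past limma that had not passed, and 4 lost a call, those of Fndc1. These alternatives reprocess the same 2 arrays on which most of the genes were chosen for a shared sign. Few reversals could therefore occur, and their absence says nothing of new samples. Signal over background of 8.76 to 10.8 limits dim genes. For 9 genes of the 1.5-fold rule, 1 labelled group was not well above background on either array.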

Other observations

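The genes in this part were chosen after their values were seen, and directions are by the dye labels. Beyond the genes named above, others passed 2-fold on both arrays. Brighter in the channel labelled Smad4cKO were the synaptic vesicle gene Syt1 (1.42 ± 0.20, log2, SE, n = 2), the protease gene Htra4 (1.16 ± 0.14), the cytokine receptor gene Il31ra (1.11 ± 0.13), Cbln1 (1.04 ± 0.13) and Sned1 (1.01 ± 0.13). Dimmer there were Tnfaip6, a hyaluronan-binding protein gene (-1.43 ± 0.20), Nwd2 (-1.19 ± 0.14), the neuropeptide gene Cartpt (-1.15 ± 0.13), Pdzrn4 (-1.14 ± 0.13), Zar1 (-1.07 ± 0.13) and the tight junction gene Cldn1 (-1.06 ± 0.13). Their limma adjusted p lay between 0.104 and 0.141, so 0 of these passed the threshold over all genes tested. From processed signals the log2 ratio of Il31ra was 2.18, the log2 ratio of Cbln1 1.92 and the log2 ratio of Htra4 1.81. Il31ra and Cbln1 were well above background in the labelled control channel on 1 array only.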
